A study of Arabidopsis thaliana with 12 samples.

How the data were processed

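Total RNA from roots of Arabidopsis thaliana was measured on an expression array in 12 samples, 6 from the wild type (WT) and 6 from the kn09 mutant, both in the Wassilevskija background. Per the labels, roots of both genotypes had been kept on MS medium with 100 mM glucose for 48 h. The labels number the samples 1 to 6 within each genotype and do not say whether they came from separate cultures, separate RNA preparations or repeat readings. The p-values therefore measure the spread between these samples, which may be technical.

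The deposited table holds 1 intensity per feature and sample on a linear scale, for 3439 features. How the authors scanned the arrays, corrected the background or scaled the intensities is not given in the sources used here. From the values, the brightest feature of every sample stands at 100, no value lies below 0, and 153 to 522 features per sample are exactly 0. Within rounding, 1 to 4 features per sample stand at 100. An intensity is thus taken here as relative to the brightest features of its own sample, although how the value of 100 arose is not known. An exact 0 says only that a feature is listed at 0. The number of arrays limits the precision. No other column of per-sample values was left aside.

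Intensities were quantile normalized between samples in limma 3.58.1 (R 4.3.3), because the sample medians differed, and put on the log2 scale. Deposited zeros, and values below the 1st percentile of the positive normalized values (an intensity of 0.0062), were set to that floor. In the first version of this step zeros kept the value that quantile normalization gave them, which differed between samples. That version called features that were 0 in all 12 samples, so it was replaced after the result had been seen, and its counts are given among the alternatives. Log2 differences are kn09 minus WT. For dim features they depend on the floor and on the quantile normalization, and understate or overstate the change, so deposited intensities stand beside them. The normalization could set similar low intensities higher in kn09 than in WT. For AT5G02050, 0.0438 in WT sample 4 became a log2 value of -5.81 and 0.0446 in kn09 sample 6 became -3.64, both above the floor.

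Each feature was tested with limma (lmFit and eBayes, 2-sided, genotype as the only term) and Benjamini-Hochberg adjustment over all 3439 features, and a feature was called at an adjusted p under 0.05. Different features of a gene were kept apart. Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01 and again with an estimated correlation, for lists with at least 3 measured members. The separation of the genotypes was the mean Pearson correlation of sample pairs within genotypes minus that between genotypes, with an exact permutation test over all labelings. The test code was run on simulated values for 3439 features with the means and spreads of these features, 50 of them changed at each of 4 fold sizes. With independent samples it recovered 12% of features changed 1.5-fold, 26% changed 2-fold, 62% changed 4-fold and 74% changed 8-fold, and 8 of 95 calls were false. With a correlation of 0.5 within pairs of samples, 53 of 144 calls were false when all samples were treated as independent, and 4 of 72 when the pairs were a random block. That block recovered 10% of features changed 2-fold and 50% changed 4-fold, and pair means recovered 0% and 26%. A call lost in these fits is thus not shown to be false.

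Gene names came from the platform annotation given with the data. It lists 1562 of the features, 692 with 1 gene and 870 with several, and 1877 features are unnamed here. Names were updated by Entrez identifier to the TAIR10.1 reference table, which matched 690 of the 692, and only features with 1 gene are named. The names were not checked against probe sequences, which were not used here. Pairs of features with the same annotation, mostly of several genes each, did not have correlated log2 differences. A name may therefore be wrong for its feature. The genome build behind the array is not given in the sources used here, so no coordinates are printed.

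The comparison, tests, alternatives, 12 gene lists and 14 name-based families were fixed before the data were examined. The rule for named genes took, among called features with 1 gene and at least 5 of 6 kn09 samples beyond the WT median, the 12 with the largest positive and the 12 with the largest negative log2 difference, plus the proline metabolism genes and the 2 members with the smallest p of every other list or family. None of the 155 loci of the 12 lists lay on a feature with 1 gene, and 3 lay on features with several. The 12 lists covered proline metabolism, nitrogen assimilation, amino acid transport, sugar transport, sugar response, mitochondrial respiration, antioxidants, water stress, defence, aquaporins, green tissue and reference genes. The result set for proline metabolism, the pathway the labels connect with kn09, was therefore not analysed here. Of the families, photosynthesis had 3 measured members, mitochondrial electron transport 2, cell wall 1 and the rest none. A further 7 lists were written from the names on the array after the brightest features had been seen and before any difference between genotypes was computed.

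The alternatives fixed beforehand were the replicate number as a fixed or random block, other normalizations, treatments of zeros and dim features, variance models, other tests and thresholds, and each sample left out. Means of consecutively numbered samples, the same pairs as a random block, and the removal of a running median over 51 neighbouring features were among those added after seeing the data. The replicate number came from the labels only, and samples that shared it across genotypes deviated together with r of 0.0683 to 0.0995, so it was not taken to pair them. In these deviations from the genotype mean, each of the 12 samples nonetheless correlated best with its own number in the other genotype, so a pairing by number stays open. As a fixed block the number gave 211 calls in place of 440.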

Results

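Expression in roots of the kn09 mutant was compared with that in wild-type roots after both had received glucose. The labels describe kn09 as hypersensitive to proline and unable to break it down in mitochondria. Gene names are those of the platform annotation, which features with a shared annotation did not bear out in their differences (r = -0.06 across 91 pairs), so each gene result holds only as far as its name does. Each genotype had 6 samples, and each sample gave 3439 feature intensities relative to its brightest features. The median intensity was 0.194 ± 0.0413 (SD, n = 6) in WT and 0.109 ± 0.00864 (SD, n = 6) in kn09. In WT, 197.3 ± 35.8 features stood at exactly 0 (SD, n = 6), against 470.5 ± 49.1 in kn09 (SD, n = 6). Each of these 2 differences had an exact 2-sided permutation p of 0.00216 over samples, and of 0.1 over means of consecutive samples, the smallest that 3 against 3 allow.

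The comparison asked which transcripts differ between kn09 and WT roots under the same treatment. AT4G13680 rose 5.12-fold in kn09 after normalization, from a deposited intensity of 1.46 ± 0.160 to 6.56 ± 1.28 (SD, n = 6 each). By the same measure AT1G01730 rose 3.35-fold, from 2.21 ± 0.479 to 6.76 ± 0.383 (SD, n = 6 each), and AT4G00170 rose 3.39-fold, from 0.360 ± 0.0548 to 0.859 ± 0.0945 (SD, n = 6 each). Z-ISO, the zeta-carotene isomerase of carotenoid synthesis, fell from 0.188 ± 0.0728 (SD, n = 6) to 0 in 5 of 6 kn09 samples, with 0.0241 in the other. CML30, a calmodulin-like protein, fell 2.14-fold after normalization, from a deposited 1.24 ± 0.286 to 0.442 ± 0.118 (SD, n = 6 each).

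In limma, 440 of 3439 features passed an adjusted p of 0.05, of which 223 were higher and 217 lower in kn09, and 1040 had an unadjusted p under 0.05. Among the 692 features with 1 gene, 31 were higher and 47 lower. The 12 samples did not overlap between genotypes in 282 of all features, or 8.2%, where chance gives 0.216% if all samples are independent. Means of consecutive samples did not overlap in 835 features, or 24.3%, where chance gives 10%. Of the 440 features, 301 differed by over 2-fold. In 5 of 6 cases consecutively numbered samples correlated more highly than any others of their genotype, the exception being kn09 samples 1 and 2. With their means as 3 values per genotype 16 features passed, 15 higher and 1 lower, while with the pairs as a random block 82 passed, 55 higher and 27 lower. On the intensities as deposited, where the median log2 difference of all features was -0.85, 99 features were higher and 1158 lower. With median scaling 451 were higher and 199 lower, and with zeros as missing 164 were higher and 350 lower. The directions below are relative to the quantile-normalized distribution, whose median difference was -0.06.

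**Figure D1:**
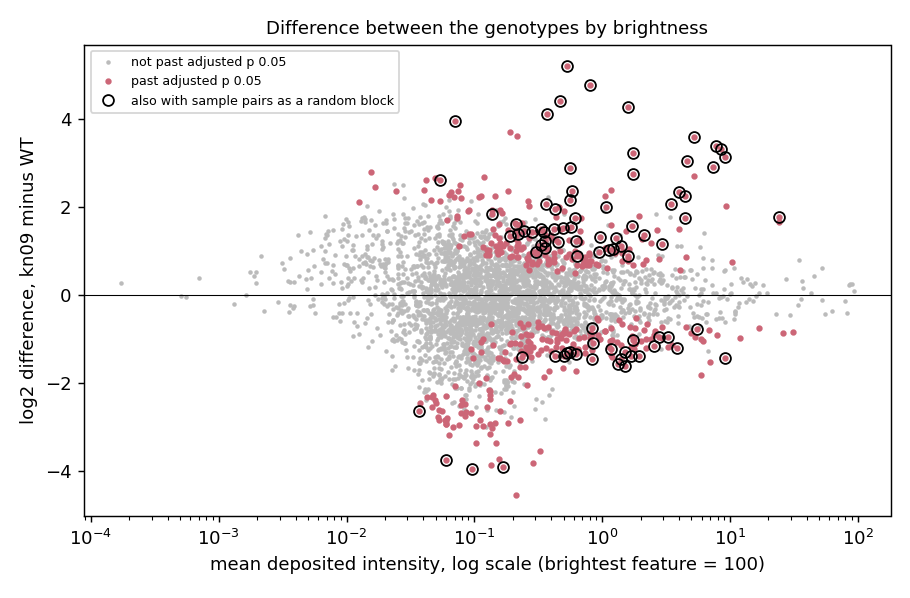
Log2 difference (kn09 minus WT, quantile normalized) of each feature against its mean deposited intensity on a log axis, for the 3431 features above 0 in at least 1 sample. Red points are the 440 features past an adjusted p of 0.05, 223 above and 217 below the line at 0, and black circles mark the 82 that also passed with sample pairs as a random block.

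Of the 12 named genes with the largest increase, 10 were above 0 in all samples, although AT5G41960 in WT sample 3 and AT1G29700 in WT sample 4 lay at the floor after normalization. AT4G13680 led them in certainty, with a log2 difference of 2.36 ± 0.16 (SE) and a limma adjusted p of 2.46e-06, and 6 of 6 kn09 samples lay above the WT median. It was also the only named gene among the 16 features that passed with means of sample pairs, with a limma adjusted p of 0.0382. AT5G33390 rose from 0.657 ± 0.701 to 1.67 ± 0.0984 and AT2G30100 from 0.629 ± 0.649 to 1.49 ± 0.152 (SD, n = 6 each). In 5 of the 12 the increase rested on WT samples 3 to 6, because WT samples 1 and 2 stood near or above the kn09 mean. These WT samples had 1.69 and 1.41 for AT5G33390, 1.46 and 1.48 for AT2G30100, 0.163 and 0.227 for AT2G23160, 0.197 and 0.269 for AT5G41960, and 0.206 and 0.195 for AT2G31800. The kn09 means of the last 3 were 0.136, 0.245 and 0.211. Without WT samples 1 and 2 the log2 differences of these 5 genes, in that order, were 3.56, 3.37, 3.45, 3.22 and 2.52 in place of 2.40, 2.25, 2.26, 2.37 and 1.87, and without WT sample 3 that of AT5G41960 was 1.77. AT1G53050 and AT1G65500 rose from WT means of 0.152 and 0.109 to 0.372 and 0.208. AT1G29700, AT5G02050 and AT1G73120 rose from WT means of 0.0589, 0.0566 and 0.0494 to 0.0982, 0.098 and 0.0889, and the last pair had WT zeros in 2 samples and in 1. WT sample 1 had 0.217 for AT5G02050, above the highest kn09 sample at 0.182. AT4G00170 completed the 12, with a log2 difference of 1.76 ± 0.18 (SE). On the intensities as deposited 6 of the 12 lost the call, while all 12 named genes with the largest decrease kept it. The median log2 difference of all features was -0.85 there, which favours lower calls, so this does not show that the decreases are firmer. With sample pairs as a random block 2 of the 12, AT4G13680 and AT4G00170, stayed called. The call was lost without some pair of samples for the other 10, and without some single sample for 7 of them (limma adjusted p up to 0.0985).

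All 12 named genes with the largest decrease were dim, with WT means under 0.5 and at least 1 kn09 sample at 0, so their fitted differences rest on the floor. With sample pairs as a random block 2 of the 12, Z-ISO and AT3G11150, stayed called, and with means of pairs 0 did in limma, where 554 of all features had an unadjusted p under 0.05. After Z-ISO, AT3G11150 fell from 0.326 ± 0.190 to 0.00901 ± 0.0109 (SD, n = 6 each), with 3 kn09 zeros. GH9B16, of a glycosyl hydrolase family, had a WT mean of 0.103 and was at 0 in 5 kn09 samples, and AGL54, an AGAMOUS-like gene, had 0.117 and was at 0 in 4. AT1G78790 (MHF2) fell from 0.216 ± 0.0883 to 0.0182 ± 0.029 (SD, n = 6 each). AT2G23890 was listed at 0 in all 6 kn09 samples and had a WT mean of 0.094, which came from WT samples 1 to 4, since WT samples 5 and 6 had 0.00182 and 0.00439. Without WT samples 1 and 2 its log2 difference was -1.86 in place of -2.55, and the call was lost (limma adjusted p = 0.12). AT5G11550, AT1G71910 and AT2G25640 fell from 0.42, 0.241 and 0.24 to 0.0367, 0.0224 and 0.0224, and without kn09 sample 6 the log2 difference of AT5G11550 was -2.24 in place of -2.84. AT3G54680, AT1G05340 and AT3G02030 had WT means of 0.146, 0.106 and 0.0914 and kn09 means of 0.00462, 0.00583 and 0.00363. The call was lost without some pair of samples for 9 of the 12, the exceptions being Z-ISO, AT3G11150 and AT3G54680, and without some single sample for 6.

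With sample pairs as a random block, 16 named features passed, 9 higher and 7 lower, and those given here were chosen after their values were seen. AT4G13680 had a limma adjusted p of 1.97e-05 in that fit, AT1G01730 0.000488, AT4G00170 0.00278 and Z-ISO 0.0137. ATSIK rose from 0.873 ± 0.265 to 1.71 ± 0.128 (SD, n = 6 each). AT1G67800, AT4G33540, AT1G74070, AT1G73470 and AT2G25830 also rose after normalization, the last by a log2 difference of 1.40 and the first by 1.43. Their deposited means went, in that order, from 0.205, 0.332, 0.752, 0.293 and 0.174 to 0.364, 0.660, 1.13, 0.554 and 0.263. For AT1G67800, WT samples 2 and 3 had a deposited 0.292 and 0.285, above kn09 samples 1 and 2 at 0.198 and 0.260. Its kn09 samples 3 to 6 lay above every WT sample. Among brighter genes that fell, AT4G39690 went from 3.64 ± 0.548 to 1.48 ± 0.462 (SD, n = 6 each), and AT4G14050 had a log2 difference of -1.56 ± 0.35 (SE). AT1G62150 fell by 1.38 on the log2 scale. AT3G54930 fell by 0.78, from 7.02 ± 0.624 to 4.05 ± 0.388 (SD, n = 6 each), and with median scaling its difference was 0.0131.

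**Figure D2:**
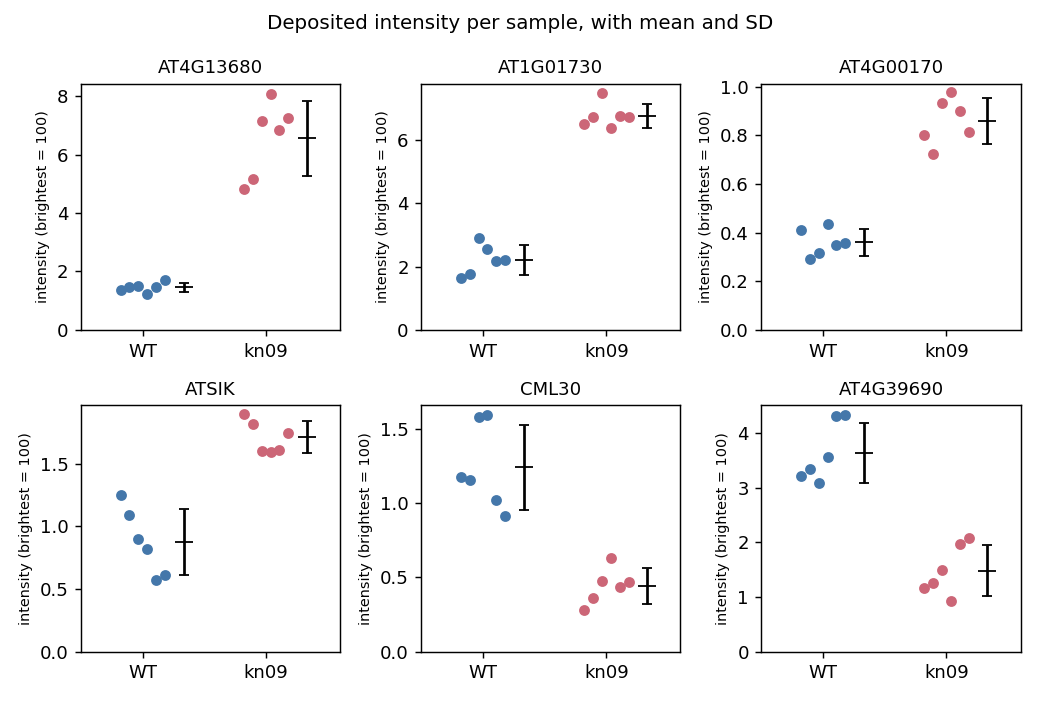
Deposited intensity (vertical axis from 0, brightest feature of a sample = 100) of 6 genes in the 6 WT and 6 kn09 samples, each point a sample, with the mean and SD at the right of each group. AT4G13680, AT1G01730, AT4G00170 and ATSIK are higher in kn09 (means 6.56, 6.76, 0.859 and 1.71), and CML30 and AT4G39690 lower (0.442 and 1.48).

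The gene groups that could be measured were mostly plastid and stress genes. None of 8 lists and families passed camera with the preset correlation (smallest adjusted p = 0.789, 0 at an unadjusted p under 0.05) or with an estimated correlation (smallest adjusted p = 0.85). In the photosynthesis family fixed beforehand, 0 of 3 members passed over all features and 1, PSBY, adjusted over the list alone. PSBY, a photosystem II subunit, had a log2 difference of 0.58 ± 0.19 (SE). LHB1B2, a light-harvesting protein, had 34.8 ± 5.44 in WT and 33.1 ± 6.78 in kn09 (SD, n = 6 each), and PSBW, of photosystem II, had 32.1 ± 8.68 and 41.9 ± 5.13. With median scaling this family and the added photosynthetic electron transport list passed in camera as higher, with limma adjusted p of 0.0272 and 0.0283.

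Among 12 genes of photosynthetic electron transport, 0 passed over all features, and 0 adjusted over the list alone. NdhS and NdhN belong to the plastid NDH complex, although the family of mitochondrial electron transport matched them by name. NdhS had 9.27 ± 2.13 in WT and 6.26 ± 0.409 in kn09, and NdhN 0.168 ± 0.0296 and 0.160 ± 0.0437 (SD, n = 6 each). Neither passed over all features and both did adjusted over that family alone, NdhN as higher (log2 difference 0.68), although its deposited mean was lower in kn09. Of 13 genes of plastid carbon and pigment metabolism, 2 rose and 1 fell, and 4 passed adjusted over the list alone. FATB, an acyl-ACP thioesterase, had a log2 difference of 0.82 ± 0.16 (SE) and PRK, the phosphoribulokinase of the Calvin cycle, 0.78 ± 0.19 (SE). For both, 6 of 6 kn09 samples lay above the WT median after normalization, while the deposited FATB intensity of kn09 samples 1 and 6 was 0.221 and 0.225 against a WT mean of 0.246, and Z-ISO was the gene that fell. SBPASE, another Calvin cycle enzyme, had a log2 difference of -0.03 ± 0.20 (SE).

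Of 10 stress and redox genes, MAMI, a mannitol-induced membrane protein, rose by a log2 difference of 0.82 ± 0.20 (SE). DRT101, named for DNA damage tolerance, had a log2 difference of -0.89 ± 0.24 (SE) and fell in that test, and the same 2 genes passed adjusted over the list alone. Of 3 histone H3 genes, AT1G13370 fell from 0.432 ± 0.0469 to 0.089 ± 0.0824 (SD, n = 6 each), over all features and adjusted over the list alone. AT1G09200, also a histone H3 gene, had a log2 difference of -0.45 ± 0.26 (SE). In the mitochondrial list 0 of 5 passed, OSB1 having -0.57 ± 0.23 (SE) and AT5G47030 0.43 ± 0.36 (SE). In plastid biogenesis 0 of 9 passed, with OTP70 at -0.65 ± 0.27 (SE) and SECE1 at -2.14 ± 0.91 (SE). In the plastid ribosome 0 of 5 passed, with AT3G13120 at 0.21 ± 0.32 (SE) and AT4G01310 at -0.09 ± 0.32 (SE). CSLA01, the lone cell wall family member, had -0.21 ± 0.25 (SE). FATB, PRK, MAMI, DRT101 and AT1G13370 did not pass with sample pairs as a random block, with limma adjusted p of 0.0661, 0.0795, 0.0829, 0.0978 and 0.19. The FATB and MAMI calls were also lost on the intensities as deposited, and those of DRT101 and AT1G13370 with median scaling. Leaving out some single sample ended the calls of PRK, MAMI, DRT101 and AT1G13370.

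Over all features, samples of one genotype correlated at a mean r of 0.841 and samples of different genotypes at 0.792. The difference of 0.0488 had an exact permutation p of 0.00216 over 924 labelings, counting those with a difference at least as high. Over means of sample pairs it was 0.0422 with an exact permutation p of 0.1, the smallest 20 labelings allow. WT samples of a consecutive pair correlated at 0.91 and other WT samples at 0.845, and the values in kn09 were 0.844 and 0.818. For kn09 samples 1 and 2 alone r was 0.817, no higher than that of other kn09 samples. Not every sample was closest to its own genotype throughout. WT sample 2 correlated at 0.817 and 0.815 with kn09 samples 3 and 4, and at 0.811 and 0.812 with WT samples 3 and 4. With WT samples 1, 5 and 6 it correlated more highly, at 0.894, 0.830 and 0.829. Genes are not independent replicates in these correlations.

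**Figure D3:**
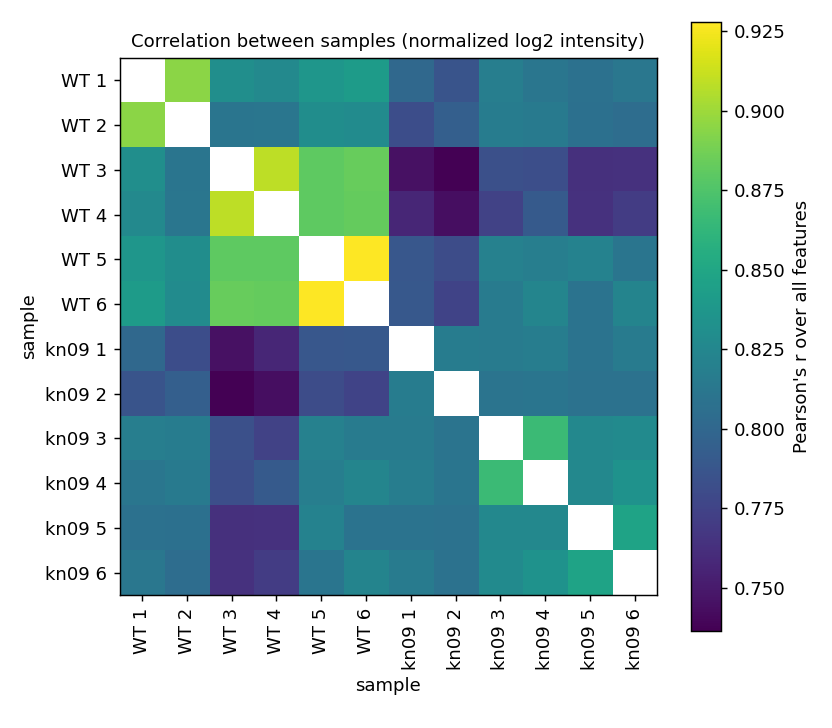
Pearson's r over all features between each 2 of the 12 samples (rows and columns, normalized log2 intensity; the diagonal is left blank). Samples of one genotype average 0.841 and samples of different genotypes 0.792, and the consecutive WT pairs stand out at a mean of 0.91.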

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

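The tests of repeat readings and of position as the whole cause were chosen only after the result was seen. Of 112 sets of 6 values checked, 3 held a sample far from the others, and chance gives about 1 in 20. Z-ISO in kn09 sample 3 stood at a normalized log2 intensity of -4.56, with the other kn09 samples at the floor of -7.33. GH9B16 in kn09 sample 2 stood at -5.18, with the others at the same floor. The deposited values were 0.0241 for Z-ISO and 0.000694 for GH9B16, against 0 in the other kn09 samples. With 5 values tied at the floor, any value above it is flagged whatever its size, so these 2 flags show nothing further. AT2G23160 in kn09 sample 6 stood at -3.62, with the others between -2.36 and -2.2.

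The count of 440 features was compared with other splits of the 12 samples: 1 of 100 splits, the real one, gave as many, and the highest of the others gave 4, so chance can be excluded for this count only if the 12 samples are independent. Averaged over a genotype, consecutive numbers were the best of the 15 pairings in both. Over all combinations of a WT and a kn09 pairing the exact permutation p was 0.00444. Deviations from the genotype mean correlated at 0.235 within WT pairs and -0.0532 within kn09 pairs, against -0.304 and -0.236 for other samples. Repeat readings of one RNA or filter, with 3 independent values per genotype, would give this order. However, kn09 samples 1 and 2 correlated at 0.817, no higher than other kn09 samples (mean 0.818). Splits that keep the pairs together number 10, too few for a share under 0.05, with 440 features for the real split and 6 for the highest other, or 16 and 0 with pair means. Position could also contribute, since neighbouring features had log2 differences correlated at 0.118, a squared r of 1.4%, and a contrast within WT had 0.139. After the running median was removed 244 of the 440 features were still called, but the log2 differences of neighbouring features still correlated at 0.0655. The removal was thus partial and does not decide whether position was the whole cause. A genotype difference stays open beside repeat readings and position.

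On the intensities as deposited, the lower calls outnumbered the higher ones, and the median log2 difference was -1.43 in the second-dimmest 25% of features and -0.30 in the brightest 25%. The gap of -1.13 between them (bootstrap 95% interval -1.25 to -0.99) argues against one scale factor per sample acting alone, which would move both alike. Zeros, more frequent in kn09, had been set to a floor, and a scale factor joined with low values set to 0 was not tested. The same value of -1.13 is consistent with an additive background that differs between the samples of the genotypes, with a median deposited difference of 0.0688. A real loss of weak transcripts in kn09 stays open and was not tested.

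The named genes that fell most were dim, and all 12 were still called after an offset of 0.0324 was added to every value. An offset leaves values at 0 the lowest, and only 3 of the 12 could be measured with zeros as missing (2 stayed called), so values set to 0 at the low end of the scale cannot be told apart from a fall. Their deposited means differed by 0.0877 to 0.383, against a median difference of 0.0688 over all features, but they were chosen as the largest called falls, so this comparison decides nothing. An additive background that differs between the genotypes stays open for their fall, as does a biological difference between kn09 and WT.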

How the results depend on the processing

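Pair means, the pair block, pairs left out, features above 0, the running median and zeros placed by quantile normalization were chosen after seeing the data. The count of 440 became 1257 as deposited, 713 with array weights, 1040 at an unadjusted p under 0.05, 16 with pair means, 82 with the random pair block and 293 without the running median. The replicate number as a fixed block gave 211 (189 shared with the 440), and in deviations from the genotype means each of the 12 samples correlated best with its own number across genotypes, a hint from the data, not the design. With single samples left out it ranged from 192 to 507: without WT 1 to 6 it was 472, 507, 192, 230, 254 and 272, and without kn09 1 to 6 240, 209, 274, 246, 250 and 279. With pairs left out it was 827, 142 and 201 for the WT pairs in order and 130, 206 and 186 for kn09. It stayed within 1.5 times in the random replicate block (540), median scaling (650), cyclic loess (452), offset (538), zeros as missing (514), dimmest 25% left out (538), trend and robust variance (580), exact Wilcoxon test (378), features above 0 (547) and zeros placed by quantile normalization (392, which called 8 features at 0 throughout). Lists passing camera went from 0 to 2 with median scaling, 1 of them contained in the other, and stayed at 0 in the other settings run (smallest adjusted p 0.0851 to 0.985). The random blocks were not run for lists, and no setting was run for proline metabolism, which had no measured member. The separation kept its side with median scaling, as deposited, loess, offset and the dimmest 25% left out, from 0.0403 to 0.0694; centring on the replicate number makes the WT and kn09 samples of a number mirror images, which inflates its 0.639 and makes it no support, and with pair means the separation was 0.0422 at the smallest p possible. No direction reversed among the 24 named genes with the largest changes, of which 15 were measured with zeros as missing, 18 with the dimmest 25% left out and 10 with features above 0; 12 to 22 stayed called with single samples left out, 24 stayed called with the offset, 18 as deposited, 13 with the replicate block, 4 with the pair block and 1 with pair means, and AT3G54930 changed sign with median scaling (0.0131). The 6 named calls lost as deposited were all among the 12 increases. The median of all features moved to -0.85 as deposited, -0.22 with zeros as missing and -0.11 with loess. For each result that moved, the cause was not tested. Signal over background is unknown, and zeros limit the dim features.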

Other observations

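The genes and features described here were chosen only after their values were seen. PSAN, of photosystem I, had 7.59 ± 1.74 in WT and 5.65 ± 1.11 in kn09, and LPA19, named for low photosystem II accumulation, 0.821 ± 0.290 and 0.341 ± 0.0904 (SD, n = 6 each), and neither passed in limma.

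Of the 16 features that passed with means of sample pairs, 15 are unnamed, and among the 16 the largest fitted folds were those of features 2704 and 2337. Feature 2704 rose 37-fold after normalization, from a deposited 0.0615 ± 0.039 to 0.996 ± 0.255 (SD, n = 6 each), and feature 2337 rose 27.5-fold, from 0.0953 ± 0.0463 to 1.52 ± 0.326 (SD, n = 6 each). Feature 4372 had 0.120 ± 0.0497 in WT (SD, n = 6) and was listed at 0 in all 6 kn09 samples.

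In 91 pairs of features with the same annotation, mostly of several genes each, the log2 differences correlated across pairs at r = -0.06 (permutation p = 0.711) and the mean levels at r = 0.284. In 2 pairs both features were called, and in 24 only 1 was. Pairs of features are not independent replicates.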
